A study of Rattus norvegicus with 8 samples.

How the data were processed

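Total RNA from 8 samples of H9c2 cells (1 of untreated cells in space, 2 of nanoceria-treated cells in space, 2 of untreated cells on ground and 3 of nanoceria-treated cells on ground) was measured on 1 rat Clariom S Pico array each. The deposited table held 1 intensity per probe set and array, made with RMA per the submitters' processing notes, and the software, its version and its settings were not given in the sources used here. The design had assumed log2 values, but the deposited intensity values were linear (8.63 to 19506, none at or below 0), so log2 was taken without a pseudocount. No background or detection measure was available, so whether a dim probe set was above background is unknown. Of 23188 probe sets, 15049 carried a single gene symbol (15037 distinct), 8139 had no symbol here and 0 had several. All symbols were matched by gene identifier to a RefSeq table, which changed 0 of them. Where 12 probe sets shared a symbol with a brighter one, the brighter stood for the gene, and all probe sets stayed in the tests.

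Differences were fitted with limma 3.58.1 in R 4.3.3, with an empirical Bayes variance and Benjamini-Hochberg adjustment at 0.05. An additive fit of regime and treatment (5 residual degrees of freedom) gave the comparisons over both treatments and over both regimes. A fit with 1 mean per group (4 residual degrees of freedom) gave nanoceria against untreated within each regime, space against ground within each treatment, and the interaction. The single array of untreated cells in space was assumed to vary like the other groups. Effects were correlated across probe sets by Pearson's r and Spearman's rank correlation, with 100 simulated draws without effects. A set of 39 gene lists (1167 entries, of which 1022 were measured and 145 were not named on the array here, with 13 genes in over 1 list) was tested with camera at a preset correlation between genes of 0.01 and adjusted over the lists in each comparison, with the correlation estimated from the data as the alternative.

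The design, the gene lists, the alternatives and the rule for naming genes were written before the data were examined. The rule named the 12 highest and 12 lowest genes past the threshold whose groups did not overlap for space against ground and for nanoceria on ground, and 6 each elsewhere. Where fewer than 4 passed, as in all 7 comparisons, it named the 4 with the smallest p in each direction. For each called list, or one discussed for its purpose, it named up to 4 members with the smallest p, and uncharacterised symbols were passed over. Of the genes so named, 2 are not reported here. The alternatives were 2 other scalings (cyclic loess, and equal array medians), the brighter 66.7% of probe sets, variance settings, array weights, a 2-fold limit, the replicate number as a block, other contrasts of the same groups, and leaving out each array in turn. Exact relabelings of the arrays and a list of zinc finger genes were added after the data were examined.

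The fits were tested on simulated data of 23188 probe sets with 200 changed. At 2-fold, 79% were recovered for space against ground, 69% for nanoceria, 34% for nanoceria on ground, 2% for nanoceria in space, 7% for space in untreated cells, 31% for space in treated cells and 0% for the interaction. At 4-fold these were 99%, 100%, 98%, 78%, 81%, 95% and 0%. With 35 unchanged genes that shared a correlation of 0.3, camera made 54 false calls in 100 draws with the preset correlation and 4 with the estimated one. Without shared correlation both made 0, and both found a log2 shift of 0.5 in 100 of 100 draws. The number of arrays therefore limited the precision, with a median standard error of 0.17 for the additive fit and 0.21 to 0.35 for the others. Ground cultures were run after the flight with its recorded temperatures, so regime and culture run could not be separated. The labels gave each array a sample of its own but did not say whether replicates were independent cultures, so p-values measure the spread between these samples. Ground untreated replicate 2 was not analysed here.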

Results

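Gene expression was profiled in H9c2 cells, a myoblast line that was derived from embryonic rat heart and that can form skeletal muscle-like myotubes. The cultures differed in gravity regime, since they were kept aboard the International Space Station or on the ground. They also differed in treatment, with 100 µg/ml of nanoceria (cerium oxide nanoparticles, studied as scavengers of reactive oxygen species) or none. Cells had been seeded at 35000 per square centimetre, travelled in a pouch preheated to 27 °C, entered a 37 °C incubator at the station on day 7 and were fixed on day 10. The ground cultures were run later with the temperature course logged in flight, so regime and culture run coincided. Total RNA, 30 ng per sample, was hybridised to rat Clariom S Pico arrays. The 8 arrays comprised 1 of untreated cells in space, 2 of nanoceria-treated cells in space, 2 of untreated cells on ground (replicates 1 and 3) and 3 of nanoceria-treated cells on ground. Each array gave an intensity for 23188 probe sets, of which 15049 carried a gene symbol here, and median intensities ran from 107 to 117. The number of arrays limited the precision, and the single array of untreated cells in space had no replicate of its own. Log2 differences are given with their standard error (SE), and group levels as mean log2 intensity with the standard deviation (SD).

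The space arrays resembled one another more than the ground arrays did. Pearson's r across probe sets, which are not independent replicates, was 0.991 to 0.992 over the 3 pairs of space arrays. It was 0.959 to 0.985 over the 10 pairs of ground arrays and 0.964 to 0.987 over the 15 pairs between regimes. Ground untreated replicate 3 stood apart in several gene lists, noticed after the values were seen. Of its 37 cell cycle genes, 34 had their lowest value of all 8 arrays there, and the list mean was -1.91 ± 0.16 (SE over genes) relative to the other 7 arrays. Plk1, a mitotic kinase, lay at -3.95, Cdc20, an activator of the anaphase-promoting complex, at -3.92 and the proliferation marker Mki67 at -2.84. Targets of NRF2, the transcription factor of the antioxidant response, lay at 1.01 ± 0.13, and 23 of 27 had their highest value of all 8 arrays there. Because this array was 1 of the 2 from untreated ground cells, values of called lists without it are given below wherever they changed a result.

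**Figure D1:**
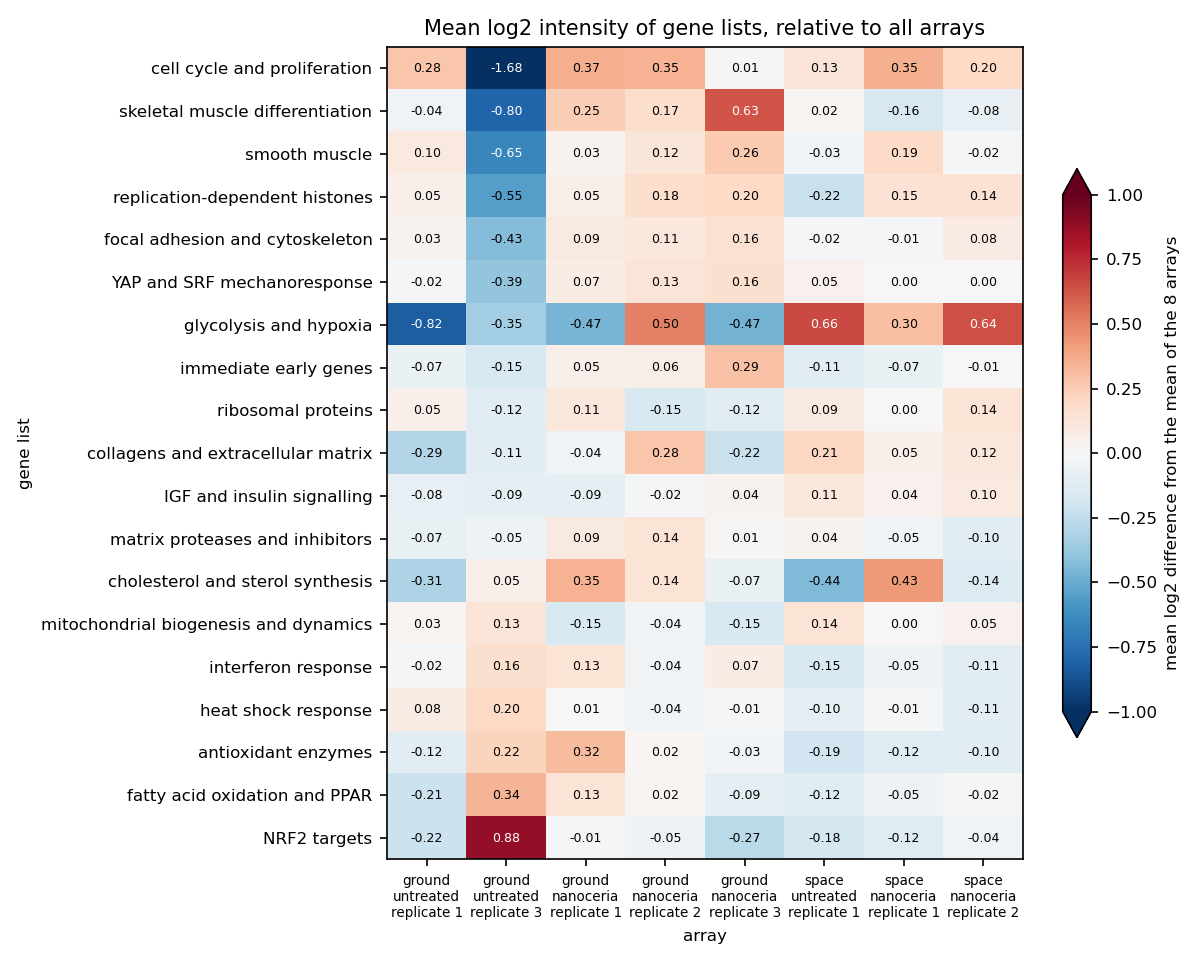
Mean log2 intensity of the 19 gene lists called in at least 1 comparison, on each of the 8 arrays (columns), as the difference from the mean of all 8 arrays, with a colour scale from -1 to 1. Ground untreated replicate 3 was lowest for the cell cycle list (-1.68) and highest for NRF2 targets (0.88), and ground nanoceria replicate 2 shared the positive glycolysis and hypoxia values of the 3 space arrays.

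Spaceflight was compared with ground over both treatments to find which genes followed the gravity regime. Glycolytic and hypoxia-responsive genes lay higher in space, by 0.84 on the log2 scale on average, with 34 of the 38 genes of the list higher. The difference was 3.32 ± 0.76 for Ero1a, an oxidase of the endoplasmic reticulum that hypoxia induces, and 1.90 ± 0.41 for the mitophagy receptor Bnip3. Higd1a, a hypoxia-inducible mitochondrial protein, differed by 1.75 ± 0.39 and Adm, which encodes the vasodilator adrenomedullin, by 1.21 ± 0.28. Ero1a levels were 7.56 ± 1.40 (SD, n = 2) in untreated and 7.98 ± 1.80 (SD, n = 3) in treated cells on ground, against 11.51 on the untreated space array and 10.94 ± 0.38 (SD, n = 2) in treated cells in space. By array, the list mean was 0.30 to 0.66 above the mean of all arrays in the 3 space samples and -0.82 to -0.35 in 4 ground samples, but 0.50 in ground nanoceria replicate 2. The list passed camera with its preset correlation (adjusted p = 7.40e-15) and in every fit that left out 1 array, with adjusted p = 0.876 with an estimated correlation. Of the 38 genes, 10 were higher when adjusted over the list alone, and 0 passed over all genes tested.

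Ribosomal protein genes were slightly higher in space, by 0.12 on average with 59 of 63 genes higher, among them Rpl39 at 0.41 ± 0.12 and Rps6 at 0.32 ± 0.11. Antioxidant enzyme genes were lower by -0.23 on average with 22 of 26 genes lower. They included Ucp2, a mitochondrial uncoupling protein, at -1.16 ± 0.20, the glutathione synthetase gene Gss at -0.73 ± 0.28 and the glutathione peroxidase gene Gpx1 at -0.40 ± 0.18. Cell cycle genes differed by 0.32 on average with 28 of 37 higher, for example Mki67 at 1.38 ± 0.58 and Cenpf, a kinetochore gene, at 1.27 ± 0.85. The camera test gave an adjusted p of 7.96e-06 for the ribosomal list and 0.0107 for each of the other two, and each had adjusted p = 0.876 with an estimated correlation. One antioxidant gene was lower when adjusted over the list alone, against 0 genes in the ribosomal and cell cycle lists. The antioxidant call ended without space untreated replicate 1 (-0.21, adjusted p = 0.0981), without ground untreated replicate 3 (-0.17, adjusted p = 0.117) and without ground nanoceria replicate 1 (-0.16, adjusted p = 0.127). The cell cycle difference was -0.020 (adjusted p = 0.751) without ground untreated replicate 3, 0.034 (adjusted p = 0.831) without space untreated replicate 1, 0.28 (adjusted p = 0.105) without ground nanoceria replicate 3 and 0.55 without ground untreated replicate 1. That call also ended under cyclic loess (0.35, adjusted p = 0.0656) and with the brighter probe sets alone (0.32, adjusted p = 0.0650).

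Single genes did not reach an adjusted p below 0.05 between space and ground with all arrays weighted equally. Among the genes with the smallest p, those higher in space included Nek1, a kinase linked to cilia and DNA repair, at 1.51 ± 0.14 (adjusted p = 0.0580), Apool, of the mitochondrial cristae-organising complex, at 0.96 ± 0.12 and Chm, a Rab escort protein, at 1.06 ± 0.16. Those lower were the kinase gene Stk38l at -1.17 ± 0.13, Ucp2 at -1.16 ± 0.20, Plekhh3 at -0.87 ± 0.15 and Taf6l, which encodes a component of histone acetyltransferase complexes, at -0.92 ± 0.17. Nek1 levels were 5.76 ± 0.30 (SD, n = 2) and 4.89 ± 0.13 (SD, n = 3) in untreated and treated cells on ground, against 7.22 and 6.43 in space. With limma and Benjamini-Hochberg adjustment, 0 of 23188 probe sets passed. At an unadjusted p below 0.05 there were 1230 higher and 987 lower, 2217 in all, where chance gives 1159. The adjusted count was 1 without ground untreated replicate 3 (Nek1, adjusted p = 0.0495) or without ground nanoceria replicate 2, and without space nanoceria replicate 1 or 2 the unadjusted count was 1310 or 1231.

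**Figure D2:**
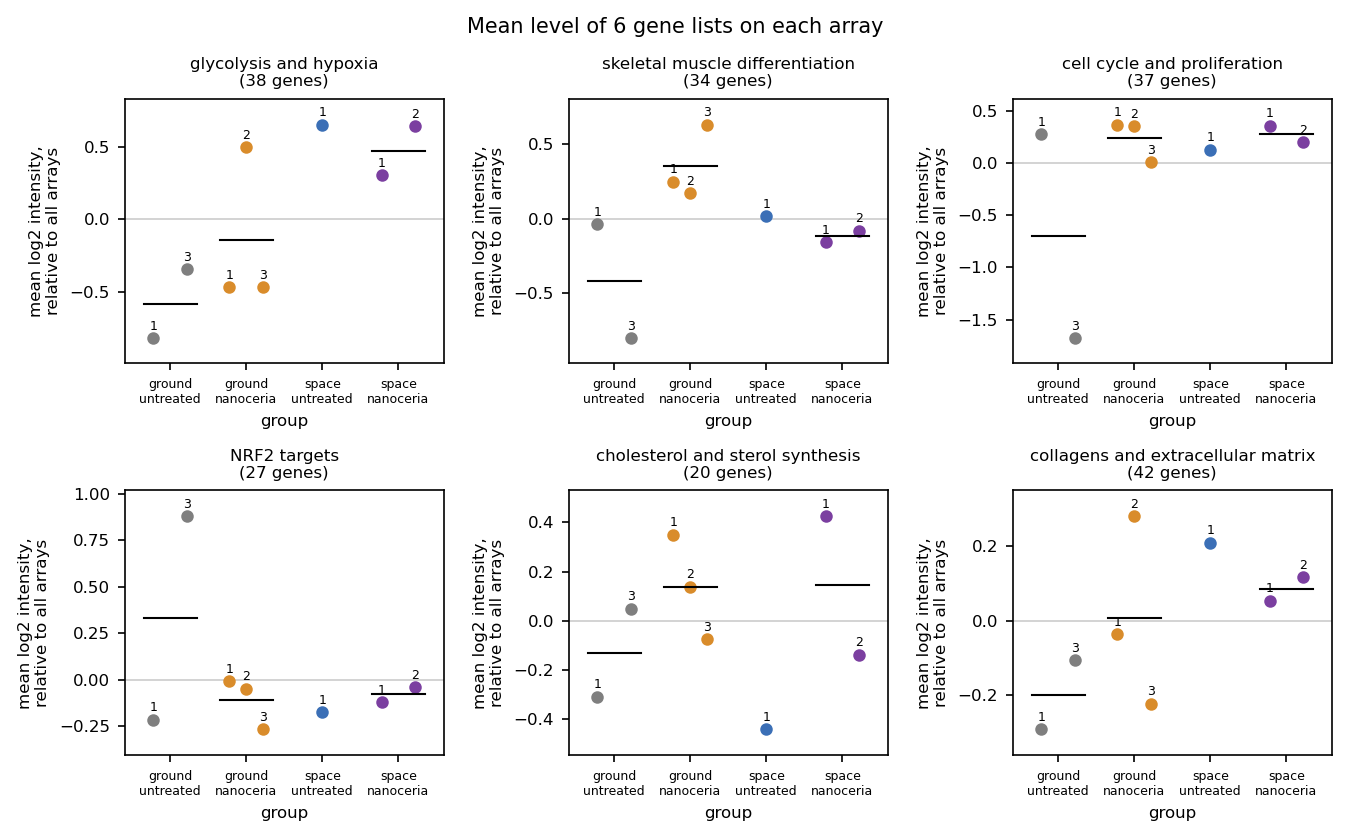
Mean log2 intensity of 6 gene lists on each array, as the difference from the mean of all 8 arrays (vertical axis), by group (horizontal axis), with points for arrays labelled by replicate and black lines for group means. The glycolysis and hypoxia list ran from 0.30 to 0.66 in space and from -0.82 to 0.50 on ground, and the skeletal muscle list from -0.80 in ground untreated replicate 3 to 0.63 in ground nanoceria replicate 3.

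Nanoceria was compared with no treatment over both regimes, with a single effect fitted for flight and ground. A call in this fit does not by itself show that an effect was common to both. Genes of cholesterol synthesis were higher with nanoceria, by 0.38 on average with 17 of 20 higher. They included Srebf2, the transcription factor that drives the pathway, at 0.75 ± 0.23, the reductase gene Dhcr7 at 1.20 ± 0.36, Fdps at 0.67 ± 0.22 and Mvk, mevalonate kinase, at 0.44 ± 0.14. In the focal adhesion and cytoskeleton list 31 of 38 genes were higher, with a mean of 0.22. Lmna, which encodes nuclear lamins A and C, lay at 0.93 ± 0.17, the integrin gene Itgb5 at 0.61 ± 0.12 and the tubulin gene Tubb6 at 0.84 ± 0.19, while the focal adhesion kinase gene Ptk2 lay at -0.55 ± 0.15. Genes of mitochondrial biogenesis and dynamics were lower by -0.16 on average with 15 of 24 lower, such as Tfb2m, a mitochondrial transcription factor, at -0.66 ± 0.17 and the fission gene Dnm1l at -0.80 ± 0.28. Camera gave adjusted p of 1.24e-04, 9.73e-04 and 0.0361 for these lists, and each had adjusted p = 0.876 with an estimated correlation. Among cytoskeleton genes 3 were higher when adjusted over the list alone, and 0 genes of the other two lists passed. Within regimes, the cholesterol list was called in space only, the cytoskeleton list on ground only and the mitochondrial list in neither. The cholesterol call ended without space untreated replicate 1 (0.27, adjusted p = 0.0613) and the cytoskeleton call without ground untreated replicate 3 (0.071, adjusted p = 0.127). The mitochondrial call ended without space untreated replicate 1, space nanoceria replicate 1, ground untreated replicate 3 or ground nanoceria replicate 3, at -0.19 (adjusted p = 0.0988), -0.16 (adjusted p = 0.0677), -0.13 (adjusted p = 0.267) and -0.15 (adjusted p = 0.0751).

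Another 7 lists were called for nanoceria over both regimes. Cell cycle genes were higher with nanoceria by 0.66 (35 of 37 higher), with the replicative helicase gene Mcm2 at 0.69 ± 0.23 and the mitotic kinase gene Aurka at 1.06 ± 0.43, and replication-dependent histones by 0.38 (9 of 9). Skeletal muscle differentiation genes were higher by 0.45 (29 of 34), with the myogenic regulator Myog at 1.32 ± 0.61 and the slow troponin gene Tnni1 at 0.95 ± 0.41, and smooth muscle genes by 0.31 (11 of 12). NRF2 targets were lower by -0.25 (21 of 27), with the cystine transporter gene Slc7a11 at -1.09 ± 0.39 and the glutathione-synthesis gene Gclc at -0.51 ± 0.23. Genes responsive to YAP and SRF were higher by 0.19 (28 of 33) and immediate early genes by 0.18 (21 of 29), for example Srf at 0.63 ± 0.21 and Fosl1 at 0.44 ± 0.13. Camera's adjusted p ran from 9.08e-07 to 0.0123 in these 7 lists, and all lost their call at adjusted p = 0.876 or, for NRF2 targets, adjusted p = 0.910 with an estimated correlation. No member of the 7 lists passed when adjusted over the list alone (0 genes). Several of the 7 lists had opposite signs by regime. Skeletal muscle genes had means of 0.77 on ground and -0.14 in space, NRF2 targets -0.44 and 0.096, and YAP and SRF genes 0.32 and -0.045. The others were higher with nanoceria in both regimes. Leaving out ground untreated replicate 3 ended every one of these calls, with means of 0.051 (cell cycle), 0.22 (histones), 0.14 (skeletal muscle), 0.074 (smooth muscle), 0.10 (NRF2 targets), 0.051 (YAP and SRF) and 0.14 (immediate early) and adjusted p from 0.0566 to 0.396. The NRF2 call also ended without ground nanoceria replicate 3 (-0.18, adjusted p = 0.0821), and so did the immediate early call (0.13, adjusted p = 0.0732). Without ground untreated replicate 1, the means were 1.08 for cell cycle genes, 0.47 for smooth muscle genes and -0.48 for NRF2 targets. Without space untreated replicate 1 they were 0.77 for skeletal muscle genes, 0.32 for YAP and SRF genes and -0.44 for NRF2 targets.

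The antioxidant enzyme list, of interest because nanoceria is used as an antioxidant, was not called for nanoceria over both regimes, with a mean of 0.062 and 17 of 26 genes higher (adjusted p = 0.454). By array, the list mean was -0.12 and 0.22 on ground untreated replicates 1 and 3, on either side of the treated ground mean of 0.10. The sign on ground thus depends on which untreated array is used. Within the list, the selenoprotein gene Selenop lay at -1.10 ± 0.29 and the peroxidase gene Gpx7 at 0.51 ± 0.20. Of single genes, those with the smallest p were Stk38l at 0.97 ± 0.13, the heparan sulphate proteoglycan gene Sdc1 at 0.72 ± 0.13, the chromatin assembly gene Chaf1b at 0.97 ± 0.18 and Lmna, all higher, and the tRNA methyltransferase gene Trmt13 at -1.48 ± 0.17, Zfp317 at -1.59 ± 0.22, Sclt1 at -1.45 ± 0.21 and Vps13a at -1.55 ± 0.22, all lower. None of them passed, and limma with Benjamini-Hochberg adjustment gave 0 genes (smallest adjusted p = 0.320). At an unadjusted p below 0.05 there were 874 higher and 1359 lower, 2233 in all, where chance gives 1159.

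On ground, nanoceria was compared with no treatment at normal gravity. Skeletal muscle genes lay higher in treated cells, by 0.77 on average with 30 of 34 higher. Acta1, skeletal alpha-actin, differed by 2.09 ± 0.47, with 8.37 ± 1.20 (SD, n = 2) in untreated and 10.46 ± 0.30 (SD, n = 3) in treated cells. Atp2a1, the fast-muscle calcium pump of the sarcoplasmic reticulum, differed by 1.48 ± 0.24, and the acetylcholine receptor subunit genes Chrna1 and Chrnd by 1.64 ± 0.35 and 1.81 ± 0.43. The list passed camera (adjusted p = 2.49e-08) and in each fit that left out 1 array, at 0.39 (adjusted p = 0.00629) without ground untreated replicate 3, with adjusted p = 0.768 with an estimated correlation. Of its 34 genes, 5 were higher when adjusted over the list alone, and 0 passed over all genes tested. Collagen and matrix genes were higher by 0.21 (34 of 42), among them elastin, Eln, at 1.21 ± 0.32, the microfibril gene Mfap5 at 0.87 ± 0.23 and the cross-linking enzyme gene Loxl1 at 0.58 ± 0.16. This call (adjusted p = 0.00618, and adjusted p = 0.768 with an estimated correlation) ended without ground untreated replicate 1 (0.11, adjusted p = 0.185) and without ground nanoceria replicate 2 (0.070, adjusted p = 0.490), and the mean was 0.32 without ground nanoceria replicate 3. Glycolysis and hypoxia genes were higher by 0.44 (29 of 38), with enolase, Eno1, at 0.81 ± 0.24 and Tpi1 at 0.88 ± 0.29 but the transcription factor gene Hif1a at -0.95 ± 0.33. That call (adjusted p = 0.00346, and adjusted p = 0.819 with an estimated correlation) also ended without ground untreated replicate 1 (0.20, adjusted p = 0.200) and without ground nanoceria replicate 2 (0.11, adjusted p = 0.517), and the mean was 0.68 without ground untreated replicate 3. In both lists 0 genes passed when adjusted over the list alone.

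Cytoskeletal genes on ground went in both directions. In the focal adhesion and cytoskeleton list 31 of 38 genes were higher with nanoceria (mean 0.32), with Tubb6 at 1.11 ± 0.19 and Lmna at 1.02 ± 0.23, while the kinase genes Rock2 at -1.94 ± 0.40 and Ptk2 at -0.73 ± 0.18 were lower. YAP and SRF genes were higher by 0.32 (27 of 33), with Srf at 0.95 ± 0.20 and the matricellular gene Ccn2 at 0.75 ± 0.26. Cell cycle genes were higher by 0.94 (34 of 37), with the helicase genes Mcm7 at 1.38 ± 0.34 and Mcm6 at 1.55 ± 0.47, histones by 0.39 (9 of 9), smooth muscle genes by 0.41 (9 of 12) and immediate early genes by 0.24 (23 of 29). NRF2 targets were lower by -0.44 (26 of 27), with the glutathione-synthesis gene Gclm at -1.14 ± 0.37 and Slc7a11 at -1.23 ± 0.51. Camera's adjusted p ran from 4.70e-08 to 0.0365 in these 7 lists, and each had adjusted p = 0.768 with an estimated correlation. Among cytoskeleton genes, 4 were higher and 2 lower when adjusted over the list alone, and 0 genes of the other 6 lists passed. Leaving out ground untreated replicate 3 ended all 7 calls, with means of 0.084 (cytoskeleton), 0.14 (YAP and SRF), -0.036 (cell cycle), 0.088 (histones), 0.037 (smooth muscle), 0.20 (immediate early) and 0.11 (NRF2 targets) and adjusted p from 0.103 to 0.858. Leaving out ground untreated replicate 1 gave 0.55 (cytoskeleton), 0.51 (YAP and SRF), 1.92 (cell cycle), 0.69 (histones), 0.79 (smooth muscle) and -0.99 (NRF2 targets). The histone call also ended without ground nanoceria replicate 2 (0.37, adjusted p = 0.135) or 3 (0.36, adjusted p = 0.0821), and the immediate early call without ground nanoceria replicate 3 (0.16, adjusted p = 0.144).

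Among single genes on ground, the smallest p belonged to Trmt13 at -1.74 ± 0.16, the lipid-transfer protein gene Vps13a at -1.93 ± 0.19 and the origin recognition gene Orc2 at -1.67 ± 0.17 (each adjusted p = 0.0892), with the vascular gene Krit1 at -1.83 ± 0.21. Higher genes were Stk38l at 1.09 ± 0.16, the co-repressor gene Trim28 at 1.09 ± 0.17, the mitotic kinesin gene Kif18b at 1.68 ± 0.26 and Atp2a1. Trmt13 levels were 6.68 ± 0.05 (SD, n = 2) in untreated and 4.94 ± 0.08 (SD, n = 3) in treated cells. With limma and Benjamini-Hochberg adjustment 0 genes passed, while an unadjusted p below 0.05 held for 1026 higher and 1523 lower probe sets, 2549 in all against 1159 by chance. Without ground untreated replicate 1, the untreated side was ground untreated replicate 3 alone, the array that stood apart in several gene lists. Trmt13 then lay at -1.71, Vps13a at -1.98 and Orc2 at -1.62, close to their values with all arrays.

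**Figure D3:**
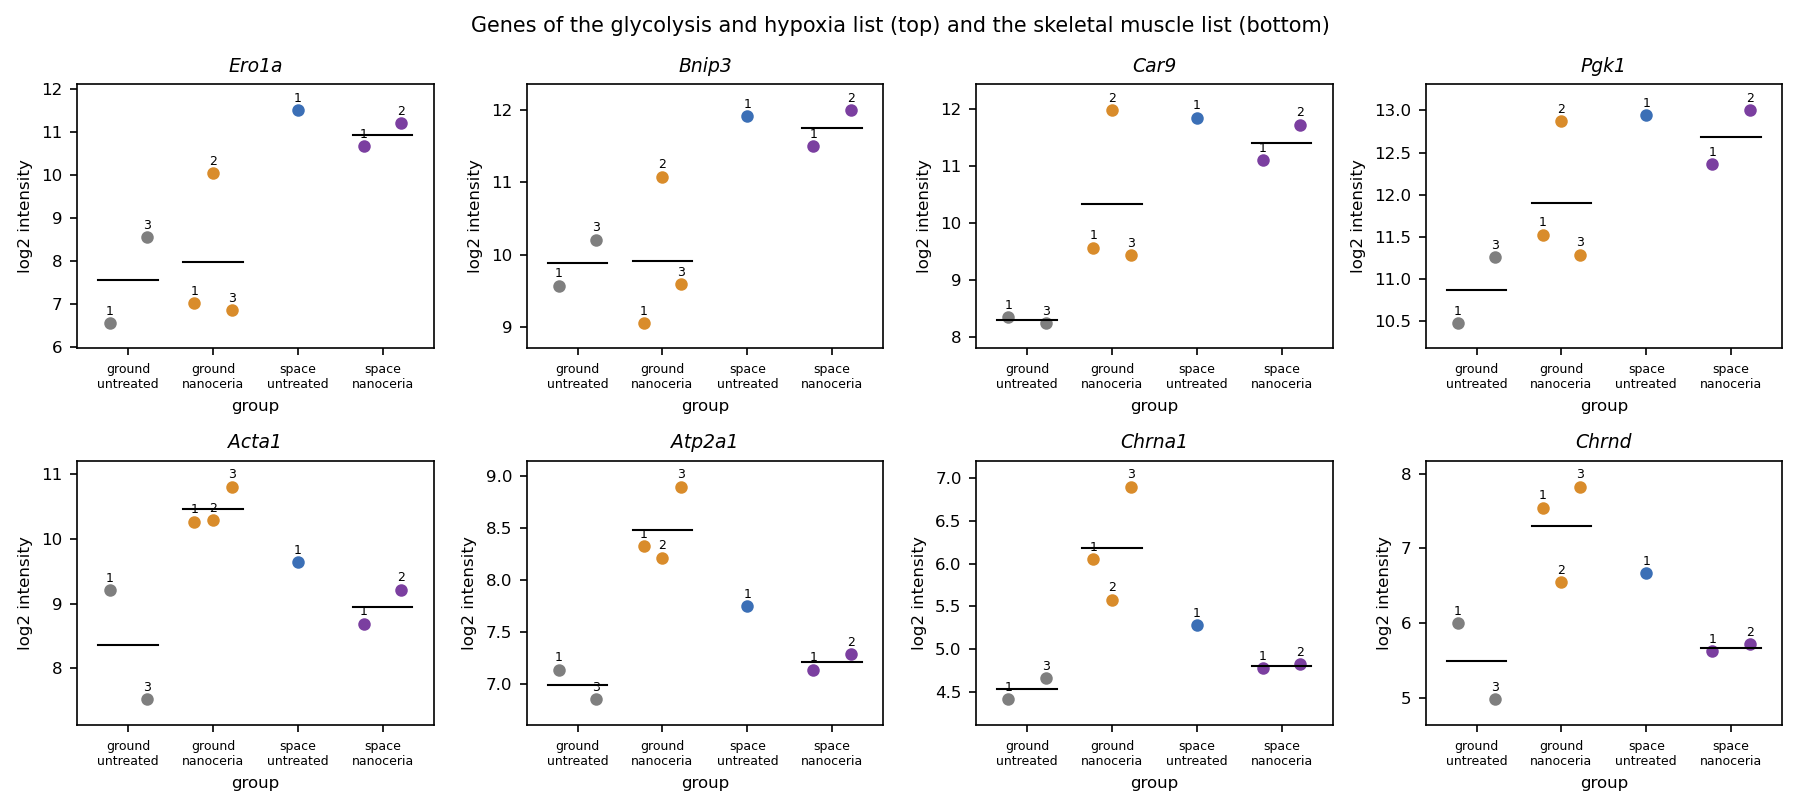
Log2 intensity (vertical axes, each with its own range) of 4 glycolysis and hypoxia genes and 4 skeletal muscle genes on each array, by group (horizontal axis), with points labelled by replicate and black lines for group means. Ero1a lay above 10 on the 3 space arrays and in ground nanoceria replicate 2 only, and Atp2a1 averaged 8.48 in treated cells on ground against 6.99 in untreated cells there.

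In space, nanoceria was compared with no treatment in flight, where the untreated side was a single array. Every one of the 20 cholesterol synthesis genes was higher with nanoceria, by 0.59 on average. The sterol oxidase gene Msmo1 differed by 1.22 ± 0.41, Srebf2 by 0.82 ± 0.40, Sqle, squalene epoxidase, by 0.78 ± 0.40 and Fdps by 0.76 ± 0.39. Relative to all arrays the list mean was -0.44 on the untreated array and 0.43 and -0.14 on nanoceria replicates 1 and 2. It passed camera (adjusted p = 2.47e-10) and held without each of the other 7 arrays, at 0.30 (adjusted p = 0.00689) without space nanoceria replicate 1, but had no value without the single untreated array, with adjusted p = 0.900 with an estimated correlation. Replication-dependent histone genes were higher by 0.37 (8 of 9), with H1f5 at 0.79 ± 0.39, a call (adjusted p = 0.0165, and adjusted p = 0.900 with an estimated correlation) that ended without space nanoceria replicate 1 (0.37, adjusted p = 0.0542). Neither list had a gene that passed when adjusted over the list alone (0 genes).

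The genes with the smallest p in space were Tppp2 at 1.01 ± 0.23, the presynaptic scaffold gene Bsn at 1.01 ± 0.23, Rassf4 at 1.02 ± 0.24 and Jmjd4 at 0.94 ± 0.23, higher with nanoceria. The lower ones were Acss3, a mitochondrial acyl-CoA synthetase gene, at -1.33 ± 0.28, Trmt13 at -0.997 ± 0.21, the sialyltransferase gene St8sia2 at -1.13 ± 0.25 and Rab38 at -0.97 ± 0.22. None passed, since limma with Benjamini-Hochberg adjustment gave 0 genes, and 341 had an unadjusted p below 0.05 (164 higher, 177 lower), where chance gives 1159. With the 3 space arrays fitted alone 1263 did, and 696 with array weights. Trmt13 thus had negative values in both regimes, at -1.74 on ground and -0.997 in space. Tppp2, Rassf4, St8sia2 and Rab38 were dim, at percentiles of mean intensity of 16, 18, 15 and 11. For every gene named in this paragraph, the untreated space array lay outside all other arrays, ground included. Trmt13 was 7.26 there and 4.87 to 6.72 elsewhere, so its value in space rests on that array. Bsn was 4.42 there and 5.34 to 5.91 elsewhere, so its values here and for space against ground in untreated cells share that departure. Skeletal muscle genes, higher with nanoceria on ground, had a mean of -0.14 in space, and NRF2 targets had a mean of 0.096.

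In untreated cells, the space array was compared with the 2 ground arrays to give the difference between regimes without nanoceria. That difference includes any difference between the culture runs. Glycolysis and hypoxia genes lay higher in space by 1.24 on average with 34 of 38 higher. The carbonic anhydrase gene Car9 differed by 3.54 ± 0.96, from 8.30 ± 0.07 (SD, n = 2) on ground to 11.84 in space, Ankrd37 by 2.67 ± 0.59, Higd1a by 2.25 ± 0.67 and phosphoglycerate kinase, Pgk1, by 2.07 ± 0.66. Collagen and matrix genes were higher by 0.41 (36 of 42), led by P4ha2 at 2.14 ± 0.71 and P4ha1 at 1.33 ± 0.56, both collagen prolyl hydroxylases, with Loxl2 at 0.81 ± 0.31 and versican, Vcan, at 0.84 ± 0.36. P4ha1 also belongs to the glycolysis and hypoxia list. These calls (adjusted p = 6.13e-22 and 1.25e-06) held without each of the other 7 arrays but could not be fitted without the single space array, with adjusted p = 0.596 and adjusted p = 0.732 with an estimated correlation. Growth factor genes Igf1 at 0.92 ± 0.26 and Igf2 at 1.73 ± 0.64 led the insulin-like growth factor list, higher by 0.20 (14 of 21). Its call (adjusted p = 0.00488, and adjusted p = 0.596 with an estimated correlation) ended without ground untreated replicate 3 (0.19, adjusted p = 0.0524). Adjusted over the list alone, 0 genes of the 3 lists passed.

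The other 12 lists called in untreated cells all lost their call without ground untreated replicate 3. Higher in space were cell cycle genes by 0.83 (36 of 37, without that array -0.15), skeletal muscle genes by 0.44 (25 of 34, 0.053), YAP and SRF genes by 0.25 (27 of 33, 0.061), smooth muscle genes by 0.25 (9 of 12, -0.13), the cytoskeleton list by 0.18 (26 of 38, -0.055) and ribosomal proteins by 0.13 (55 of 63, 0.044). Examples were Mki67 at 1.83 ± 1.03, the myogenic regulator Myf5 at 0.70 ± 0.19, the YAP partner Tead1 at 0.99 ± 0.27 and desmin, Des, at 0.87 ± 0.27. Myf5 was dim on every array, with log2 intensities from 4.01 to 4.75 where array medians were 6.75 to 6.87. Lower were NRF2 targets by -0.51 (23 of 27, without that array 0.040), cholesterol synthesis genes by -0.31 (15 of 20, -0.13), antioxidant enzymes by -0.25 (20 of 26, -0.078), heat shock genes by -0.23 (16 of 19, -0.17), interferon response genes by -0.22 (20 of 33, -0.13) and fatty acid oxidation genes by -0.18 (18 of 26, 0.092). Among them were the ferritin gene Fth1 at -0.61 ± 0.22, the small heat shock protein gene Hspb1 at -0.91 ± 0.33, the interferon regulator Irf7 at -1.48 ± 0.41 and Cpt1a, the gate of mitochondrial fatty acid import, at -1.40 ± 0.42. Camera's adjusted p ran from 8.48e-09 to 0.0493 with the preset correlation and from 0.596 to 0.851 (adjusted p) with an estimated correlation, and from 0.297 to 0.798 without ground untreated replicate 3. Adjusted over the list alone, 0 genes of these 12 lists passed.

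In these untreated cells, leaving out ground untreated replicate 1 instead gave a larger difference in each of those 12 lists. This follows by arithmetic from the values without replicate 3, since the main value is the mean of both, and is no further result. The means were then 1.80 for cell cycle, 0.82 for skeletal muscle, 0.44 for YAP and SRF, 0.62 for smooth muscle, 0.41 for cytoskeleton and 0.21 for ribosomal protein genes, and -1.06 for NRF2 targets, -0.49 for cholesterol synthesis, -0.42 for antioxidant, -0.30 for heat shock, -0.31 for interferon response and -0.46 for fatty acid oxidation genes. Smooth muscle and fatty acid oxidation genes also lost their calls without any array of nanoceria-treated cells, with adjusted p from 0.0516 to 0.0706 and unchanged means. The cytoskeleton call likewise ended without ground nanoceria replicate 3 (adjusted p = 0.0553) and the interferon call without ground nanoceria replicate 2 (adjusted p = 0.0547). Under cyclic loess the calls for smooth muscle (0.23, adjusted p = 0.139), cytoskeleton (0.17, adjusted p = 0.234), ribosomal protein (0.077, adjusted p = 0.123) and interferon response genes (-0.19, adjusted p = 0.0580) ended. Single genes with the smallest p included haptoglobin, Hp, at 1.44 ± 0.23, Nek1 at 1.47 ± 0.24 and Mmachc at 1.17 ± 0.21, higher in space, and the xanthine dehydrogenase gene Xdh at -1.59 ± 0.26, Bsn at -1.32 ± 0.23, Csad at -1.20 ± 0.22 and C8h3orf18 at -0.99 ± 0.20, lower. None passed, as limma with Benjamini-Hochberg adjustment gave 0 genes and 728 with an unadjusted p below 0.05 (379 higher, 349 lower), against 1159 by chance. The counts were 6 and 1811 without ground untreated replicate 1, and without replicate 3 the unadjusted count was 1442.

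In nanoceria-treated cells, 2 space arrays were compared with 3 ground arrays to give the difference between regimes, and so between culture runs, under treatment. Glycolysis and hypoxia genes lay higher in space, by 0.62 on average with 31 of 38 higher. Bnip3 differed by 1.84 ± 0.55, Adm by 1.20 ± 0.38, the angiogenic factor gene Vegfa by 0.98 ± 0.31 and Ero1a by 2.96 ± 1.00. Skeletal muscle genes lay lower in space by -0.47 with 28 of 34 lower. They included Atp2a1 at -1.27 ± 0.24, Chrna1 at -1.38 ± 0.35, Chrnd at -1.63 ± 0.43 and Tnni1 at -1.57 ± 0.41. With camera the adjusted p was 4.76e-06 and 4.28e-04, both calls held without each array in turn, and both had adjusted p = 0.955 with an estimated correlation. Without ground nanoceria replicate 2, the glycolysis and hypoxia mean was 0.94. Ribosomal protein genes were higher by 0.12 (51 of 63), with Rpl39 at 0.51 ± 0.15, a call (adjusted p = 0.00135, and adjusted p = 0.955 with an estimated correlation) that ended without space nanoceria replicate 2 (0.052, adjusted p = 0.392), ground nanoceria replicate 2 (0.074, adjusted p = 0.164) or ground nanoceria replicate 3 (0.092, adjusted p = 0.103). The ribosomal mean was 0.19 without space nanoceria replicate 1 and 0.20 without ground nanoceria replicate 1. Adjusted over the list alone, 1 muscle gene was lower and 0 genes of the other lists passed.

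Under treatment, the single genes with the smallest p between regimes were Nek1 at 1.53 ± 0.18, Trmt13 at 1.32 ± 0.16, Krit1 at 1.67 ± 0.21 and Orc2 at 1.29 ± 0.17, higher in space. Those lower in space were Stk38l at -1.28 ± 0.16, the methionine adenosyltransferase gene Mat1a at -1.04 ± 0.18, Atp2a1 at -1.27 ± 0.24 and Ccdc8 at -0.74 ± 0.14. Trmt13, Krit1, Orc2, Stk38l and Atp2a1 were also named for nanoceria on ground, which shares the treated ground arrays. Krit1 averaged 7.43 on those arrays, against 9.26 in untreated cells on ground. In space it was 9.45 untreated and 9.10 treated. Orc2 averaged 6.31 there, against 7.98, 8.13 and 7.60. For these genes the treated ground arrays stood apart, rather than the space arrays. Limma with Benjamini-Hochberg adjustment gave 0 genes (smallest adjusted p = 0.280), and 1950 had an unadjusted p below 0.05 (1163 higher, 787 lower) against 1159 by chance. Without space nanoceria replicate 1 or 2 that count was 990 or 1023.

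Whether the effect of nanoceria differed between regimes was tested as an interaction, the nanoceria effect in space minus that on ground. Skeletal muscle genes had a mean interaction of -0.91 with 30 of 34 negative, from 0.77 on ground to -0.14 in space. The interaction was -2.77 ± 0.78 for Acta1, -2.02 ± 0.39 for Atp2a1, -2.80 ± 0.71 for Chrnd and -2.12 ± 0.59 for Chrna1. Acta1 levels were 9.64 on the untreated and 8.95 ± 0.37 (SD, n = 2) on the treated arrays in space. Collagen genes gave -0.33 (36 of 42 negative), with Eln at -1.32 ± 0.53, and glycolysis and hypoxia genes -0.62 (31 of 38), with Car9 at -2.46 ± 1.19. These calls (adjusted p = 3.34e-11, 1.75e-04 and 5.62e-05) held without each of 7 arrays but had no value without space untreated replicate 1, and each had adjusted p = 0.890 with an estimated correlation. The muscle mean was -0.52 without ground untreated replicate 3, the collagen mean -0.19 without ground nanoceria replicate 2, and the glycolysis mean -0.30 without ground nanoceria replicate 2 and -0.38 without ground untreated replicate 1. Adjusted over the list alone, 1 muscle gene and 0 genes of the other two lists passed.

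The remaining interactions called were cell cycle genes at -0.79 (32 of 37 negative), NRF2 targets at 0.54 (24 of 27 positive), YAP and SRF genes at -0.37 (28 of 33 negative), the cytoskeleton list at -0.26 (30 of 38) and matrix proteases and inhibitors at -0.25 (16 of 24). Examples were Mcm7 at -1.18 ± 0.57, Gclm at 1.62 ± 0.61, Ajuba at -0.92 ± 0.29, Rock2 at 1.72 ± 0.68 and the aggrecanase gene Adamts4 at -1.54 ± 0.53. Camera's adjusted p ran from 1.46e-05 to 0.0404, and each had adjusted p = 0.890 with an estimated correlation. Without ground untreated replicate 3 the first 4 calls ended, at 0.18 (adjusted p = 0.580), -0.012 (adjusted p = 0.999), -0.18 (adjusted p = 0.0594) and -0.028 (adjusted p = 0.605), and without ground untreated replicate 1 the means were -1.77, 1.09, -0.56 and -0.49. The cytoskeleton call also ended without space nanoceria replicate 1 (-0.22, adjusted p = 0.0682), and the protease call without space nanoceria replicate 2 (-0.22, adjusted p = 0.0880), ground untreated replicate 1 (-0.24, adjusted p = 0.124), ground nanoceria replicate 1 (-0.24, adjusted p = 0.0556) or ground nanoceria replicate 2 (-0.22, adjusted p = 0.114). Adjusted over the list alone, 0 genes of these 5 lists passed.

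Of single genes, Ccdc62 at 2.37 ± 0.47, the adhesion molecule gene Alcam at 1.68 ± 0.34, Hltf, a DNA translocase gene, at 1.84 ± 0.42 and Xdh at 1.40 ± 0.32 had the smallest p among positive interactions. Atp2a1, the hydrogen sulphide-producing enzyme gene Cth at -1.30 ± 0.30, Fam161a at -1.52 ± 0.36 and Rab38 at -1.16 ± 0.27 had the smallest among negative ones. Fam161a and Rab38 were dim, at percentiles of mean intensity of 18 and 11, and both were highest on the untreated space array. By limma with Benjamini-Hochberg adjustment 0 genes passed, and 545 had an unadjusted p below 0.05 (335 positive, 210 negative), fewer than the 1159 that chance gives. Without ground untreated replicate 1 or 3 the unadjusted count was 1282 or 1330, and without space nanoceria replicate 1 it was 343.

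The differences between space and ground with and without nanoceria were positively correlated, but not beyond what relabelled arrays gave. Across the 23188 probe sets, which are not independent replicates, the space effect in untreated cells correlated with that in treated cells at Pearson's r = 0.332 (Spearman's coefficient 0.258), and 59.3% had the same sign. The 2 contrasts shared no array, and simulated unchanged groups gave r between -0.022 and 0.024. An exact relabeling of the arrays within treatment gave a value as high in 4 of 30 arrangements (one-sided p = 0.133). For nanoceria, the effect on ground correlated with that in space at r = 0.30 (Spearman's coefficient 0.240), with 58.2% of the same sign, and no other of the 30 arrangements within regime reached it (exact one-sided p = 0.0333, the smallest they can give). Without ground untreated replicate 3 the space correlation was 0.194. Trmt13, Stk38l and Chaf1b had nanoceria differences of the same sign in both regimes. They were named for a small p over both regimes, which favours such genes, so they add no evidence of agreement. Chaf1b levels were 8.88 ± 0.27 (SD, n = 2) untreated and 10.07 ± 0.17 (SD, n = 3) treated on ground. In space they were 8.94 and 9.52 ± 0.24 (SD, n = 2), a smaller difference.

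Lists for other processes and cell types were not called in any comparison with all 8 arrays. Of the 39 lists, 20 were called in none of the 7 comparisons, with means between -0.23 and 0.24. Some of them were called for space in untreated cells without ground untreated replicate 1, a fit with a single array on either side. Markers of fibroblasts ran from -0.15 to 0.24 (lowest adjusted p = 0.0807), those of endothelial cells from -0.17 to 0.16, of immune cells from -0.13 to 0.0065, of neurons and glia from -0.14 to 0.11 and of epithelia from -0.070 to 0.11. Iron handling genes, of interest beside a metal oxide, ran from -0.23 to 0.16 (lowest adjusted p = 0.0740) and metallothioneins with their metal response from -0.078 to 0.11. Oxidative phosphorylation ran from -0.088 to 0.096, p53 and DNA damage genes from -0.13 to 0.14, apoptosis from -0.14 to 0.098, and lysosome and autophagy from -0.14 to 0.085. Ground untreated replicates 1 and 3 differed, at -0.38 and 0.44 for lysosome, -0.19 and 0.45 for iron handling and -0.14 and 0.32 for p53 genes. The untreated space array lay between them (-0.10, -0.097 and -0.033), so the sign of that difference depends on which ground array is used. The atrophy and proteasome list, of interest in muscle cells under reduced loading, ran from -0.049 to 0.11, and cardiac muscle genes from -0.14 to 0.19. The others were lists of adipogenesis, circadian clock, endocytosis, inflammation, Notch and Wnt signalling, TGF-beta and BMP signalling, and unfolded protein response genes.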

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

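Of the tests below, the relabeling of the muscle interaction was written before its result was seen, while the cyclic loess fit as a test of it, the fit without ground untreated replicate 3 as a test of it and the other relabelings were chosen after.

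The effect of nanoceria differed between space and ground in 8 gene lists by camera with its preset correlation, each with adjusted p = 0.890 with an estimated correlation. Skeletal muscle genes had an interaction of -0.91 (0.77 on ground, -0.14 in space). NRF2 targets had 0.54 (-0.44 on ground, 0.096 in space). Cell cycle genes had -0.79 (0.94 and 0.15). Collagen and matrix genes had -0.33 (0.21 and -0.12). Matrix proteases and inhibitors had -0.25 (0.14 and -0.11). YAP and SRF genes had -0.37 (0.32 and -0.045). The focal adhesion and cytoskeleton list had -0.26 (0.32 and 0.057). Glycolysis and hypoxia genes had -0.62 (0.44 and -0.18). Relabeling all 8 arrays exactly gave p from 0.0321 for the proteases to 0.611 for cell cycle genes, and adjusted p = 0.996 for all 8 lists. Each of these values rested on the single array of untreated cells in space and on the 2 of untreated cells on ground, among which ground untreated replicate 3 stood apart. The values without each array that ended or moved a call are given with the interaction above.

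Of these, the muscle interaction (-0.91) was weighed further. Rescaling the deposited values did not account for it, since it was -0.90 ± 0.15 (SE over genes) under cyclic loess. The scaling already in the deposited values could not be tested this way. Without ground untreated replicate 3 the interaction was -0.52 ± 0.14 (SE over genes), so its sign did not come from that array alone. Each untreated group then held a single array, and the SE over genes does not measure the spread between arrays. Whether the remainder exceeds that spread could therefore not be decided. Chance assignment of the arrays stays open, because 1680 exact relabelings gave p = 0.164. A regime-dependent effect of nanoceria on myogenic genes is a candidate explanation that these arrays leave untested against a difference between individual cultures.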

How the results depend on the processing

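All alternatives here were planned. Of 797 alternative values of the 56 named-gene results, 790 kept direction and side of the threshold, 7 came to pass it and 0 reversed. None of these results had passed in the main fit, so none could lose a call. The genes were named for a small p in the same arrays, which makes a reversal unlikely. These counts therefore say little about how stable the gene results are. Of 747 values of the 52 list calls, 592 kept both, 143 were no longer called and 12 reversed. With the estimated correlation 0 lists were called in each of the 7 comparisons. Cyclic loess ended 5 of the 52 list calls, the brighter probe sets 6, array weights 2 (skeletal muscle at 0.22 and NRF2 targets at -0.14 for nanoceria over both regimes) and equal array medians 1 (fatty acid oxidation genes at -0.17 in untreated cells). The mean of the simple contrasts ended 1 of 14, and the arrays of the groups compared alone 4 of 30. The brighter probe sets left 1 list for nanoceria in space (fewer genes were tested), with agreements of 0.385 for the space effect and 0.382 for the nanoceria effect. With array weights limma gave 4 genes for space against ground, among them Nek1 (adjusted p = 0.00789), Stk38l (adjusted p = 0.0349) and Apool (adjusted p = 0.0407). An unadjusted p with at least 2-fold gave 235 genes there, 223 for nanoceria over both regimes, 620 for nanoceria on ground, 44 for nanoceria in space, 190 for space in untreated and 415 in treated cells, and 240 for the interaction, as this threshold takes no account of the number of genes. The mean of the simple contrasts gave 7 lists for space against ground, and the arrays of the groups compared alone gave 6 for nanoceria in space. Elsewhere the cause was not tested.

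With the replicate number as a block, cell cycle genes in space against ground reversed to -0.10 (adjusted p = 0.390), and 6 lists were called for nanoceria in space and 9 for space in untreated cells. The block ended 11 list calls in all. Deviations of same-numbered ground arrays correlated at -0.296 and -0.348, but with 2 untreated arrays these mirror the values of differently numbered ones, and no space pair was checked. Nothing here showed that the numbers pair the samples.

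Leaving out 1 array gave 0 to 1 genes and 3 to 8 lists for space against ground, 5 to 12 lists for nanoceria over both regimes, 0 to 167 genes and 6 to 18 lists for nanoceria on ground, 1 to 4 lists for nanoceria in space, 0 to 6 genes and 5 to 21 lists for space in untreated cells, and 6 to 18 lists for the interaction. The highest gene counts for nanoceria on ground and for space in untreated cells came without ground untreated replicate 1. Ground untreated replicate 3 was then the only untreated ground array. The agreement ranged from 0.194 to 0.361 for the space effect and from 0.234 to 0.326 for the nanoceria effect. Lists that reversed did so without ground untreated replicate 3, given first, with the value at the other end of their range without ground untreated replicate 1. For nanoceria on ground, space in untreated cells and the interaction, these ends mirror each other around the main value by arithmetic. Cell cycle genes ranged from -0.020 to 0.55 in space against ground, from -0.036 to 1.92 for nanoceria on ground (camera, which compares with all other genes, kept its direction there), from -0.15 to 1.80 in untreated cells and from 0.18 to -1.77 in the interaction. NRF2 targets ranged from 0.10 to -0.48 for nanoceria over both regimes, from 0.11 to -0.99 on ground, from 0.040 to -1.06 for space in untreated cells and from -0.012 to 1.09 in the interaction. In untreated cells, smooth muscle genes ranged from -0.13 to 0.62, the cytoskeleton list from -0.055 to 0.41 and fatty acid oxidation genes from 0.092 to -0.46. Leaving out the single space array of untreated cells left its comparisons without a value.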

Other observations

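Of the tests below, the count of splits at an unadjusted p and the cyclic loess fit for cell cycle genes were written before their results were seen, while the other tests and the zinc finger list were chosen after.

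Ground untreated replicate 3, low in cell cycle and muscle genes, was high in lysosomal, stress and detoxification genes. Lysosome and autophagy genes lay 0.50 ± 0.080 (SE over genes) above the other 7 arrays, with 33 of 40 higher, among them the glycoprotein gene Gpnmb at 1.71 and the cathepsin genes Ctsd at 1.05 and Ctsb at 1.02. The p53 and DNA damage list lay 0.37 ± 0.13 higher (16 of 22 higher, 6 lower), with the cell cycle inhibitor Cdkn1a at 0.92, Gadd45a at 1.57 and the ribonucleotide reductase subunit Rrm2b at 1.72. Of the NRF2 targets, the epoxide hydrolase gene Ephx1 lay at 2.50, Gsta1 at 2.18, Osgin1 at 2.13 and heme oxygenase, Hmox1, at 1.24. Members in the other direction were Gadd45b at -0.91, Bbc3 at -0.21, Bax at -0.17 and Ddb2 at -0.15 of the p53 list, the autophagy gene Map1lc3a at -0.51 and the NRF2 target Ugdh at -0.21, among others. Troponin C of fast muscle, Tnnc2, lay at -3.88 and Myog at -2.81. These genes were picked after their values were seen.

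Zinc finger genes, many of which repress transposons and other genes, were noticed for low values with nanoceria on ground, so that these values do not test the pattern. They were taken by the symbol prefixes Zfp, Zbtb, Zkscan, Zscan and Znf. Of 210 such genes, 130 were lower and 80 higher, with a mean of -0.24 (camera adjusted p = 7.41e-05, and adjusted p = 0.739 with an estimated correlation). Leaving out each ground array in turn gave means from -0.29 to -0.19. In space the mean was -0.060, and the interaction was 0.18 (camera adjusted p = 0.00569, and adjusted p = 0.879 with an estimated correlation). The interaction contains the ground difference for which the list was chosen, so it does not test the pattern either. Over the arrays the mean was 0.17 and 0.066 in untreated cells on ground and -0.22, -0.072 and -0.074 in treated cells.

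The higher glycolysis and hypoxia genes in space were weighed against technical explanations. Rescaling the deposited values did not account for them, since the difference was 0.87 ± 0.13 (SE over genes) under cyclic loess. The scaling already in the deposited values could not be tested this way. Chance assignment of the arrays stays open, as exact relabeling within treatment gave a two-sided p = 0.1 for the list, where 0.0333 was the smallest that 30 arrangements can give. Regime and culture run coincided, so a difference between the runs stays open as well. Lower oxygen at the cells in flight is a candidate explanation that no oxygen measure here could test.

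The low cell cycle genes of ground untreated replicate 3 were weighed as well. Rescaling the deposited values did not account for them, since the list lay at -1.95 ± 0.16 under cyclic loess. The scaling already in the deposited values could not be tested this way. Of the marker lists, neuronal and glial genes lay at 0.098 ± 0.14 (6 of 12 lower) and immune genes at 0.065 ± 0.059 (8 of 17 lower), both with members on either side. Fibroblast genes lay at -0.16 ± 0.18 (9 of 12 lower). Endothelial genes lay at -0.24 ± 0.088 (10 of 12 lower) and epithelial genes at -0.17 ± 0.055 (11 of 11), so neither list was raised there on average. Smooth muscle genes lay at -0.75 ± 0.14 (12 of 12 lower), cardiac muscle genes at -0.27 ± 0.11 (15 of 20) and the adipogenesis list at 0.15 ± 0.078 (15 of 23 higher). Levels of the brightest marker of each of the first 5 lists there, and as the mean of the other 7 arrays, were 9.58 and 8.20 for Map2, 8.39 and 8.14 for Cd14, 11.64 and 11.62 for Pdgfrb, 9.57 and 9.85 for Eng and 11.38 and 11.52 for Krt8. Cells of another type stay open, since the level that a share of them would give is not known here. A culture that had left the cell cycle, or a sample that was mislabelled or handled apart, may also explain the values, and neither was tested.

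Chance could not be excluded for the counts of genes at an unadjusted p over all 8 arrays. For space against ground, 7 of 55 splits of the arrays into groups of the same sizes gave as many genes at an unadjusted p (2217, highest other 3206), and for nanoceria 5 of 55 did (2233, highest other 3886). At an adjusted p both counts were 0, which all 55 splits reach by construction, so they decide nothing about chance. The highest other count was then 3 for space against ground and 56 for nanoceria. The split with 56 genes set the 3 space arrays, ground untreated replicate 1 and ground nanoceria replicate 3 against the rest. Regime was a term of that fit, so it compared ground untreated replicate 1 and ground nanoceria replicate 3 with the other ground arrays only. This split was picked as the highest after the counts were seen, and its cause was not tested. Exact relabeling of list means within treatment or regime gave a smallest adjusted p = 0.520 for regime and 0.433 for nanoceria, but with 0.0333 as the smallest p that 30 arrangements can give, a small number of lists could not pass after adjustment over 39.

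Contrasts that share arrays correlate by construction. Nanoceria on ground against space in treated cells, which share the 3 treated ground arrays, correlated at r = -0.719, where groups without effects gave -0.400, with a covariance of -0.106 against -0.0263. Nanoceria in space against space in untreated cells, which share the single untreated space array, correlated at -0.563, where groups without effects gave -0.667. The remaining pairs gave 0.205 (nanoceria on ground against space in untreated cells) and -0.178 (nanoceria in space against space in treated cells), where groups without effects gave 0.447 in both. The simulated groups all had the same spread for a gene. The median SD of the arrays was 0.11 in treated cells in space, against 0.19 untreated and 0.22 treated on ground. A shared group with a smaller spread gives a lower correlation without effects, so the gap to 0.447 for treated cells in space is overstated.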
